A study of Mus musculus with 20 samples.

How the data were processed

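RNA was measured from 7 clonal fibroblast lines of mouse Swiss 3T3 origin on a 3' oligonucleotide expression array, in 20 arrays. Per the labels' protocols, the cells were still dividing at harvest, in medium with bovine serum that does not induce differentiation. Total RNA was primed with oligo-dT, transcribed in vitro into biotinylated RNA and hybridized to 1 array per sample. Per the labels, 4 lines were preadipose (Swiss 2, Swiss 8 and Swiss 9 with 3 arrays each, Swiss 19 with 2) and 3 were non-adipogenic (Swiss 3, Swiss 5 and Swiss 22 with 3 arrays each). Nothing in the labels said whether arrays of a line came from separate cultures, so a p-value made from the spread between arrays of a line measures only that spread, which may be technical.

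The deposited values were linear intensity values of probe sets, from 0 upward, and the summarization and scaling used to make them are not given in the sources used here. They were not on a common scale between arrays. The mean intensity of the brightest array was 6.11 times that of the dimmest, and the log2 medians of the arrays differed by 0.607. Detection calls and scan dates were not used here. The table held 45101 probe sets, 64 of them controls. Of the probe sets, 34958 were paired with 1 gene symbol and 932 with several in the platform annotation. Of the 45037 probe sets that were not controls, 9160 were not named here. Gene identifiers of 34754 probe sets matched the gene table of the GRCm38.p6 assembly, which changed 0 symbols. That table was also used to find which genes neighbour each other, and none of its coordinates are given, because no genome build was named for the array.

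Values were taken as log2(intensity + 32). Because the log2 medians differed by more than the 0.2 allowed in advance, the arrays were quantile-normalized. A gene was represented by the probe set with the highest mean over all arrays among those with 1 symbol, which left 18193 genes, and no filter on dim genes was used. The pseudocount of 32 compressed the log2 differences of dim genes. For readable levels, each array was also scaled linearly to a trimmed mean of 500, with 2% trimmed at each end, and these values are called scaled intensity. Folds are ratios of class means of scaled intensity over lines. A line was counted as above background for a gene when its scaled intensity exceeded the 95th percentile of 27 unspiked bacterial control probe sets, averaged over its arrays. Where no line of a class was above background, the class was set to that background, or to its own value where higher, and the fold is written as at least that large. Where only some lines of the dimmer class were above background, its other lines were set to background in the same way, a step added after the data were seen.

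The clonal line was the replicate of the class comparison. Arrays were averaged within a line, and the 7 line means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences among the lines of a class were tested with limma's moderated F test on all 20 arrays with 1 term per line. For 29 gene lists, camera was run on the line means with a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were run beside it. The lists held 734 entries, of which 687 matched a measured gene. Entries were matched by symbol, and 1, Bmal1, by a synonym that no other gene carries as its symbol. For the lists, names and members were fixed before the data were examined, as were the main tests, the alternatives not named as added and the rule for named genes. The share of each gene's sum of squares between classes, between lines of a class and between arrays of a line was taken without a test. An exact two-sided permutation test over all 35 assignments of the 7 line means was run for Zfp423, and the lowest p it can give is 0.0286.

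The rule for named genes had 4 parts. Zfp423 was named in every case. The 10 genes with the largest log2 difference in each direction were named among those past the threshold whose line means did not overlap between the classes. From each list, up to 4 called members were named, or, with none called, up to 2 members without overlap of line means. Among genes called by the F test within a class, the 5 with the largest range of line means were named. Clone and predicted names were passed over in the second and the fourth part. Genes named outside the rule are said to be so where they appear.

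No scan batch was recorded in the sources used here, so arrays were split at the largest gap in the mean log2 level of 9 hybridization-spike probe sets, a gap of 1.61-fold. This gave 11 dim arrays, all those of Swiss 2, Swiss 8 and Swiss 9 and a pair from Swiss 3, and 9 bright arrays, those of Swiss 5, Swiss 22 and Swiss 19 and the remaining array of Swiss 3. Because both parts held both classes, the class fit was repeated on 8 means of line and part with the part as a block, and within each part. Swiss 3 entered this block as 2 means, which were treated as independent, so the block was also fitted on 7 means with Swiss 3 by its dim arrays alone and by its bright array alone. Residual degrees of freedom were 5 with 8 means and 4 with 7. Without normalization between arrays and with arrays centred on their medians, lists and genes were also set against genes of like mean level, the 200 genes nearest in mean over all arrays. That comparison itself takes out shifts that depend on level, much as quantile normalization does, so its match with the fit reported is no separate evidence. The split into dim and bright arrays, the fits made with it and the comparison with genes of like mean level were added after the data were seen. Replicate numbers ran within lines, and nothing in the labels said that they paired arrays of different lines.

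The scripts were tested on simulated data for the 18193 genes. In the class comparison, 96 of 100 genes changed by 1 on the log2 scale and 100 of 100 genes changed by 2 were recovered, with 15 false calls. In 20 simulations of the class comparison without changed genes, the highest number of calls was 0. The F test among 4 simulated lines, with no spread between lines apart from the shifted line, recovered 97 of 100 genes changed by 1 and 100 of 100 changed by 2, with 16 false calls. In the simulation of camera, 1 of 1 shifted list was recovered. Genes were simulated as independent of each other. The simulations therefore do not show how the calls, those of lists above all, fare where genes move together. The alternatives covered the replicate unit, the normalization, the pseudocount, a filter on the lower 40% of genes, the choice of probe set, the variance prior, a minimum fold of 1.5, a threshold of 0.1, and leaving out each line and each array. The number of lines, 4 and 3, limits the precision of every class difference.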

Results

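Gene expression was compared between clonal lines of Swiss 3T3 cells, an immortalized mouse embryo fibroblast strain, to find genes that mark fibroblasts committed to become fat cells before differentiation starts. Preadipose lines, able to become adipocytes, were Swiss 19, Swiss 9, Swiss 8 and Swiss 2, and the other 3, Swiss 22, Swiss 5 and Swiss 3, were non-adipogenic. Of the 20 arrays, 11 came from preadipose and 9 from non-adipogenic lines. All cells were harvested while dividing. Their profiles followed the clonal lines closely. For 19 of 20 arrays the most similar array was of the same line, and all 7 lines were most similar to a line of their own class. Correlations between arrays of a line ran from 0.969 to 0.992 over the 10916 brighter genes, and those between arrays of different lines from 0.894 to 0.984.

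The arrays differed in brightness, and brightness was not balanced between the classes. Mean intensity ran from 25.6 on an array of Swiss 2 to 156.7 on an array of Swiss 19. By the level of the hybridization spikes, which were added in equal amounts by design of the assay, the 20 arrays fell into 11 dim and 9 bright ones. The dim arrays held 3 of the preadipose lines, and the bright arrays held Swiss 19 with Swiss 5 and Swiss 22. Swiss 3 was on both sides. Counts of called genes, and list medians and calls that changed, are therefore given with this split as a block and within its parts as well.

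**Figure D1:**
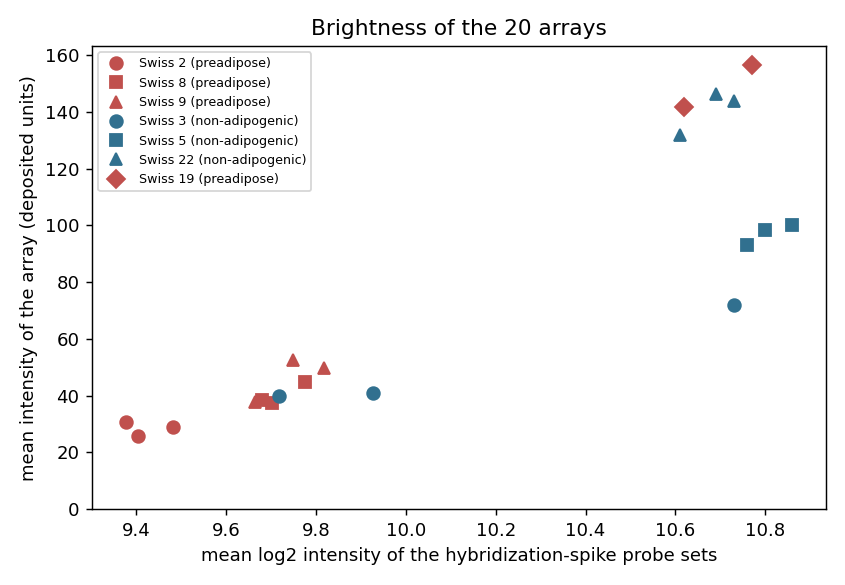
Mean intensity of each of the 20 arrays (vertical axis, deposited units) against the mean log2 intensity of its hybridization-spike probe sets (horizontal axis), with a point per array, red for preadipose and blue for non-adipogenic lines, and a shape for each line. The 11 dim arrays reach 9.93 on the horizontal axis and the 9 bright arrays start at 10.61, with 1 array of Swiss 3 among the bright ones.

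Zfp423, a zinc finger transcription factor known to regulate preadipocyte commitment, was at background in all 7 lines on its only named probe set. Its scaled intensity was 44.8 in Swiss 2, 24.6 in Swiss 8, 41.4 in Swiss 9 and 53.2 in Swiss 19, against 28.8 in Swiss 3, 8.78 in Swiss 5 and 3.09 in Swiss 22. The background of the unspiked controls lay between 76.9 and 144 in these lines. Only 1 of the 20 arrays exceeded its own background. The class means were 41.0 ± 11.99 (SD, n = 4 lines) and 13.6 ± 13.5 (SD, n = 3 lines). The log2 difference was 0.09 with a standard error of 0.050 and did not pass the threshold (limma, adjusted p = 0.473). Near background this size depended on the settings without passing in any: it was 0.92 with the smaller pseudocount and 0.65 with scaling before the pseudocount (adjusted p = 0.266 in both), 0.21 with arrays centred on their medians, 0.031 within the dim arrays and 0.024 with the larger pseudocount. The exact two-sided permutation test gave p = 0.0857 with 35 assignments. No fold is given, because both classes were below background.

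The genes with the largest excess in preadipose lines over non-adipogenic lines included secreted proteins, enzymes and signalling proteins. Lgals3, which encodes the lectin galectin-3, had a scaled intensity of 4705 ± 2538 (SD, n = 4) in preadipose lines and was not above background in any non-adipogenic line, at least 50.9-fold higher (log2 difference 3.12 ± 0.35 SE, limma adjusted p = 0.0120). Efemp1, a fibulin of the extracellular matrix, was at least 27.6-fold higher, at 2549 ± 969, with no non-adipogenic line above background (adjusted p = 0.00665). Lpl, the lipase that releases fatty acids from circulating lipoproteins, was 10.5-fold higher, at 3242 ± 1566 against 310 ± 218 (SD, n = 3 lines; adjusted p = 0.0410). Igfbp4, which binds insulin-like growth factors, was 9.68-fold higher, at 6038 ± 1381 against 624 ± 155 (adjusted p = 0.00439). Thbd, the thrombin receptor thrombomodulin, was at least 17.97-fold higher, with 2 of 3 non-adipogenic lines above background. Slpi, a secreted protease inhibitor, was 5.28-fold higher, and Fah, an enzyme of tyrosine breakdown, 5.65-fold. The stress-responsive transcription factor Atf5 was 3.71-fold higher. Cdc42ep3, a Cdc42 effector, was 3.91-fold higher, and Grb14, an adaptor that inhibits the insulin receptor, 3.40-fold. For these 10 genes all 4 preadipose line means lay above all 3 non-adipogenic ones, and adjusted p ran up to 0.0469, the value of Atf5.

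The genes lower in preadipose lines included receptors, a peptide hormone and an oxidase subunit. Cck, the peptide hormone cholecystokinin, fell from 7293 ± 2453 in non-adipogenic to 824 ± 539 in preadipose lines, at least 8.78-fold lower (log2 difference -2.61 ± 0.39 SE, adjusted p = 0.0286). Swiss 2 was the only line in which Cck was not above background. Cyba, the membrane subunit of the phagocyte NADPH oxidase, was at least 21.9-fold lower and was above background in no preadipose line (adjusted p = 0.0193). Pdgfra, a receptor for platelet-derived growth factor found on fibroblast progenitors, was 5.08-fold lower, at 5251 ± 1456 against 26667 ± 3401 (adjusted p = 0.00505). Its log2 difference of -2.27 was shared in sign by all 3 of its probe sets. S1pr3, a sphingosine-1-phosphate receptor, was 3.54-fold lower. Smoc2, a secreted calcium-binding matrix protein, was at least 22.4-fold lower, with 2 of 4 preadipose lines above background, and Fibin, a secreted factor, was 14.6-fold lower. Htra1, a secreted serine protease, was 5.59-fold lower, and Cdo1, which oxidizes cysteine, 8.42-fold. Akap12, a kinase scaffold, was 3.75-fold lower. Fam43a was 4.62-fold lower and had the smallest adjusted p of the 20 genes, 0.000609.

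**Figure D2:**
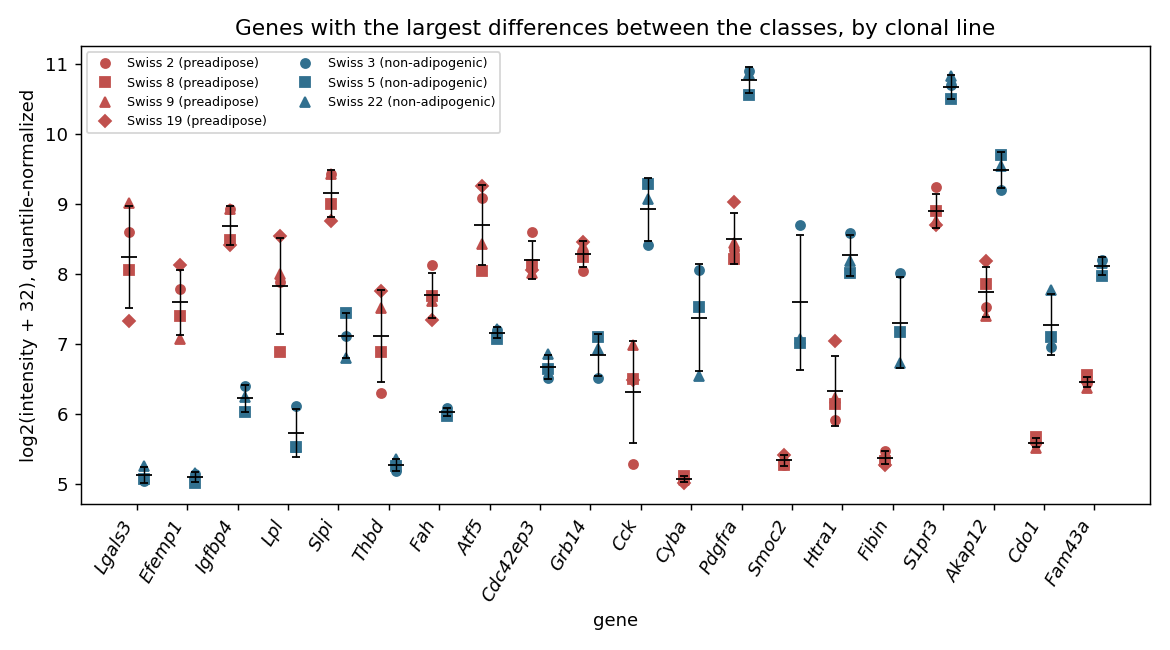
Levels of the 20 genes with the largest differences between the classes, as quantile-normalized log2(intensity + 32) (vertical axis) for each gene (horizontal axis), where each coloured point is the mean of a clonal line, red for the 4 preadipose and blue for the 3 non-adipogenic lines, and black bars give class means ± SD over lines. In no gene do the line means of the classes overlap, and the log2 differences run from 3.12 for Lgals3 to -2.61 for Cck.

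In total, 106 genes were higher and 173 lower in preadipose lines among 18193 genes tested (limma on 7 line means, adjusted p below 0.05), and 2842 had an unadjusted p below 0.05. On scaled intensity, 50 of the 106 and 84 of the 173 differed by at least 2-fold. Line means of the classes did not overlap for 2533 genes, or 13.9%, and all 279 called genes were among these. Chance gives 5.71% as an average over the 35 splits of the lines. Genes move together, so the share of a single split can lie far from that average. The count of called genes rested on quantile normalization. With arrays centred on their medians it was 1 higher and 6 lower, and without normalization 0 higher and 2 lower, with the median of all genes shifted by -0.19. Relative to genes of like mean level the median size of the 279 differences was 0.63 as reported and 0.64 in both of these scalings, while the median standard error was 0.0875 as reported, 0.372 with median centring and 0.534 without normalization. Both scalings must give the same 0.64, because median centring shifts all genes of an array alike. The comparison with genes of like mean level takes out shifts that depend on level, much as quantile normalization does. The 279 genes were also picked after that normalization. The like sizes were therefore largely set in advance and do not show that the calls are robust. With brightness as a block, in 8 means of line and part to which Swiss 3 gives 2, 136 genes were higher and 178 lower. With Swiss 3 entered by its dim arrays alone the block gave 101 and 138, and by its bright array alone, which leaves the dim part without a non-adipogenic line, 11 and 8. Within the dim arrays, where Swiss 3 stands alone against 3 preadipose lines, 189 were higher and 189 lower. Within the bright arrays, where Swiss 19 stands alone against 3 lines, limma called 0 in each direction and 1575 had an unadjusted p below 0.05. In both of these fits the lone line is assumed to vary like the others. Sizes of single genes could differ between the parts. Within the dim and the bright arrays the log2 difference was 3.51 and 2.19 for Lgals3, 1.56 and 2.76 for Lpl, and -2.51 and -1.21 for Htra1. Leaving out a line gave 104 calls without Swiss 2, 85 without Swiss 8, 131 without Swiss 9, 81 without Swiss 3, 59 without Swiss 5, 55 without Swiss 22 and 470 without Swiss 19. Of the 20 genes named above, 10 passed the threshold whichever line was left out, namely Efemp1, Igfbp4, Slpi, Fah, Cdc42ep3, Grb14, Pdgfra, S1pr3, Cdo1 and Fam43a. Of the 23 other called list members named below, 3 did so (Lum, Loxl1 and Cdkn2c), Trib3 and Angpt1 passed in none of these fits, and Fst, Smad3, Fbln5, Hoxa7 and Tbx15 did not pass with brightness as a block. With Swiss 3 by its dim arrays alone in the block, these 5 and Lpl, Atf5, Cck, Trib3, Foxa2, Gli3, Tgfbr2, Col6a3, Angpt1 and Shox2 did not pass. With the spike level as a covariate none of these passed either, nor did Cyba, Smoc2, Htra1, Bmal1, Wwtr1, Vcam1, Wnt5a, Fzd4, Ifit2 and Meis1. Probe sets of a gene differed in size: in Grb14 (0.079), Tgfbr2 (-0.0011), Wnt5a (-0.0072), Meis1 (-0.056), Gli3 (-0.11) and Fbln5 (-0.11) another probe set had a far smaller log2 difference than the one used.

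None of the 3 lists on fat cell formation was called. Of 26 measured adipogenic regulators, 1 was called, over all genes: Bmal1, the circadian clock factor listed as Arntl, was 2.85-fold higher in preadipose lines (adjusted p = 0.0258), though only 1 of its 2 probe sets had that direction. Adjusted over the list alone, 1 was higher and 1 lower. Of 28 measured anti-adipogenic regulators, 2 were called higher and 2 lower. Trib3, a stress-induced pseudokinase, was 2.54-fold higher, and Foxa2, a forkhead factor, at least 4.73-fold higher with 1 of 3 non-adipogenic lines above background. Gli3, an effector of Hedgehog signalling, was 2.05-fold lower, and Wwtr1, the Hippo pathway coactivator TAZ, 1.43-fold lower. Adjusted over the list alone, 2 were higher and 7 lower. Of 28 measured genes of mature adipocytes, only Lpl was called. Camera gave these 3 lists adjusted p of 0.687, 0.456 and 0.388.

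Called members of the signalling and surface marker lists were mostly lower in preadipose lines. Of 19 measured progenitor surface markers, Pdgfra and Vcam1, an adhesion receptor, were lower, Vcam1 by 2.33-fold (5853 ± 1377 against 13641 ± 674, adjusted p = 0.0214). In the BMP list, 1 of 30 members was called: Fst, the secreted antagonist follistatin, was 2.61-fold lower, and 23 of 30 members had negative differences. In the TGF-beta list, the receptor Tgfbr2 was 1.81-fold and the signal transducer Smad3 1.44-fold lower among 20. Smad3 (adjusted p = 0.0492) was not called with the replicate block (adjusted p = 0.0526), was called in 8 of 20 fits with an array left out, and of the fits with a line left out only in that without Swiss 19. In the Wnt list, the ligand Wnt5a was 2.56-fold lower (adjusted p = 0.0153) and the receptor Fzd4 2.30-fold lower among 46, the latter in 2 of its 3 probe sets. Igfbp4 was the only called member of 32 in the FGF and IGF list, and Gas1, a Hedgehog co-receptor, the only one of 23 in the Notch and Hedgehog list, 2.04-fold lower (15921 ± 3270 against 32409 ± 2665). Adjusted over the list alone, 1 gene was higher and 4 lower in the BMP list, 2 and 3 in the TGF-beta list, 0 and 5 in the Wnt list, 3 and 2 in the FGF and IGF list, 0 and 3 in the Notch and Hedgehog list and 0 and 2 among surface markers. In the fit over all lines camera called none of these lists, the lowest adjusted p being 0.0919 for the BMP list. It called the BMP list downward without the dimmest genes (adjusted p = 0.0232, and adjusted p = 0.654 with an estimated correlation) and with the line as a random block (adjusted p = 0.0182). Fry, which asks whether a list's genes move one way on balance, called the BMP list (adjusted p = 0.0159) and the Wnt list (adjusted p = 0.0169). Camera with an estimated correlation called neither (adjusted p = 0.42 for both). In the TGF-beta and the Notch and Hedgehog list the median was positive while the mean and the test were negative.

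Matrix genes moved in both directions. Col6a3, a chain of collagen VI, was 3.01-fold higher in preadipose lines, the only called gene of 20 collagens. Among 37 measured matrix glycoproteins and remodelling genes, Efemp1 was higher and 3 were lower: Lum, a small proteoglycan, by at least 7.10-fold with 2 of 4 preadipose lines above background, Loxl1, an enzyme that crosslinks elastin, by 1.88-fold, and Fbln5, a fibulin of elastic fibres, by 1.94-fold. Adjusted over the list alone, 1 collagen was higher, and 2 matrix genes were higher and 4 lower. Camera called neither list in the fit over all lines (adjusted p = 0.456 and 0.4). It called collagens upward with the spike level as a covariate (adjusted p = 0.0376, and adjusted p = 0.775 with an estimated correlation) and within the bright arrays (adjusted p = 1.91e-08, and adjusted p = 0.788 with an estimated correlation). With arrays centred on their medians it called matrix glycoproteins and remodelling genes downward (adjusted p = 0.0282, and adjusted p = 0.782 with an estimated correlation).

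Positional identity genes had called members in 1 direction only. Hoxa7 was at least 3.62-fold lower in preadipose lines, with 2 of 4 of them above background, and was the only called gene of 33 measured HOX genes. The homeobox factors Shox2 (1.74-fold) and Meis1 (1.96-fold) and the T-box factor Tbx15 (1.96-fold) were lower, the 3 called among 38 other mesoderm patterning factors. Adjusted over the list alone the counts were the same, 1 and 3. Camera gave adjusted p of 0.173 and 0.122, and fry called the patterning list (adjusted p = 0.0179), which camera with an estimated correlation did not (adjusted p = 0.42). Without the dimmest genes camera called HOX genes downward (adjusted p = 0.0232, and adjusted p = 0.664 with an estimated correlation). Among 22 measured imprinted genes none was called. Plagl1 was at least 13.1-fold lower (adjusted p = 0.122) and Ndn 2.53-fold higher (adjusted p = 0.267), neither past the threshold, and 1 probe set of each went the other way.

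No list of markers of other cell types was called by camera in the fit over all lines. Angpt1, a ligand of the endothelial receptor Tie2, was 2.31-fold higher in preadipose lines and was the only called gene of 15 pericyte markers. No gene was called among 20 contractile, 20 skeletal muscle, 14 osteoblast, 17 chondrocyte, 18 endothelial, 17 macrophage and leukocyte, 18 epithelial and 16 neural and glial markers. Adjusted over the list alone, 1 pericyte marker and 1 leukocyte marker were higher, and none of the others was called. Myog and Col10a1 were above background in no line, Mymk and Cybb in 1 line each, and Plvap in 3 preadipose lines. Snorc was at least 1.62-fold lower (adjusted p = 0.185), Csf1r 1.42-fold higher (adjusted p = 0.0825), Ocln at least 1.23-fold lower (adjusted p = 0.456) and Tubb3 at least 2.16-fold higher (adjusted p = 0.0946). Tubb3 passed with brightness as a block (adjusted p = 0.0426), but not with Swiss 3 by its dim arrays alone in that block (adjusted p = 0.0595). Without normalization between arrays Csf1r differed by -0.090, where genes of like mean level had a median difference of -0.36. Without normalization, camera called contractile and pericyte markers upward (adjusted p = 0.0494 for both, and adjusted p = 0.966 for both with an estimated correlation). With arrays centred on their medians it called pericyte, chondrocyte and neural and glial markers upward (adjusted p = 0.0282, 0.0306 and 0.0282, and adjusted p = 0.582, 0.663 and 0.582 with an estimated correlation). With the spike level as a covariate it called contractile genes upward (adjusted p = 1.27e-10, and adjusted p = 0.14 with an estimated correlation). Camera called contractile and smooth muscle genes upward also with brightness as a block (median log2 difference 0.35, adjusted p = 0.000113) and within the bright arrays (median 0.60, adjusted p = 1.35e-09), where Swiss 19 was the only preadipose line. Both calls were lost with an estimated correlation (adjusted p = 0.839 and adjusted p = 0.788), and over all lines adjusted p was 0.388, or 0.862 with an estimated correlation. The median of this list was -0.29 without normalization and -0.17 with arrays centred on their medians, where genes of like mean level had -0.55 and -0.42.

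Cell cycle genes were higher and interferon response genes lower in preadipose lines by camera, although the cell cycle median was -0.26 without normalization between arrays and -0.13 with arrays centred on their medians, where genes of like mean level had medians of -0.61 and -0.48. Relative to those genes the cell cycle list was 0.28 higher, with 29 of 31 members above them. Both scalings must give this same value, because median centring shifts all genes of an array alike. The comparison also takes out shifts that depend on level, much as quantile normalization does, so it is no separate evidence. Camera's direction was upward without normalization (adjusted p = 0.0249, lost with an estimated correlation at adjusted p = 0.966) and with median centring (adjusted p = 0.509). Of 31 measured cell cycle genes 29 had positive differences, with a median log2 difference of 0.33 (camera adjusted p = 1.76e-05), but no member was called over all genes or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.862). Pcna, the DNA polymerase clamp, was 1.79-fold higher (adjusted p = 0.0847) and Mcm3, of the replicative helicase, 1.90-fold (adjusted p = 0.169). Of 24 interferon response genes 20 had negative differences, with a median of -0.14 (adjusted p = 0.0389, and adjusted p = 0.862 with an estimated correlation). Ifit2, an interferon-induced antiviral protein, was the only called member, 2.06-fold lower, and 3 members were lower adjusted over the list alone. In Swiss 3 the mean of the cell cycle list lay 0.74 below the mean of the 7 lines (-0.742) and that of the interferon list 0.548 above it. Without Swiss 3 the medians were 0.074 (adjusted p = 0.25) and 0.020 (adjusted p = 0.936). The interferon call was lost as well without Swiss 2 (median -0.14, adjusted p = 0.0539), without Swiss 8 (-0.12, adjusted p = 0.0862), without normalization between arrays (-0.34, adjusted p = 0.0711) and with scaling before the pseudocount (-0.28, adjusted p = 0.0584). Without normalization, genes of like mean level had a median of -0.30, the interferon list lay -0.10 from them, and 10 of its 24 members were above them, against 4 of 24 in the fit reported. The medians with brightness as a block were 0.47 (adjusted p = 3.04e-08) and -0.26 (adjusted p = 0.000359). Within the dim arrays, where Swiss 3 is the only non-adipogenic line, they were 0.99 and -0.55 (adjusted p = 1.69e-21 and 4.68e-08), and within the bright arrays 0.13 and -0.028 (adjusted p = 0.157 and 0.154). With an estimated correlation, adjusted p was 0.841 for both lists with the block and 0.595 for both within the dim arrays.

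Of the remaining lists none was called by camera in the fit over all lines. Median, mean and camera's direction also differed in sign for anti-adipogenic regulators (median 0.0071, mean -0.029, downward), osteoblast markers (median -0.0084, mean -0.014, upward), p53 targets and cell cycle inhibitors (median 0.062, mean -0.012, upward) and reference genes (median -0.051, mean 0.058, downward). Among 21 cell cycle inhibitors and p53 targets, Cdkn2c, an inhibitor of the kinases that open the cell cycle, was 4.07-fold lower in preadipose lines (1099 ± 189 against 4477 ± 1258, adjusted p = 0.0109), the only called member, also when adjusted over the list alone. Of 22 chemokines and cytokines none was called. Cxcl12 was 1.71-fold lower (adjusted p = 0.117), with 1 of its 3 probe sets going the other way, and Il6 2.44-fold higher (adjusted p = 0.124). Il6 passed with brightness as a block (adjusted p = 0.0492), but not with Swiss 3 by its dim arrays alone in that block (adjusted p = 0.084). Hmgcs1, of cholesterol synthesis, was 1.45-fold lower (adjusted p = 0.161), and none of the 18 genes of that list was called. Camera called the cholesterol list downward without normalization (adjusted p = 0.0249), with arrays centred on their medians (adjusted p = 0.000242), with the spike level as a covariate (adjusted p = 0.0139) and within the bright arrays (adjusted p = 0.00221). With an estimated correlation these calls were lost, at adjusted p = 0.966, 0.663, 0.775 and 0.788. Among 14 reference genes none was called over all genes, but adjusted over the list alone 4 were higher and 2 lower. With arrays centred on their medians camera called this list downward (adjusted p = 0.0285, and adjusted p = 0.782 with an estimated correlation), where genes of like mean level had a median of -0.57, as the list did. Pgk1 was 1.65-fold higher (adjusted p = 0.0710) and Cyc1 1.55-fold (adjusted p = 0.0760). Without normalization between arrays they differed by -0.049 and -0.13, where genes of like mean level had a median difference of -0.71.

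**Figure D3:**
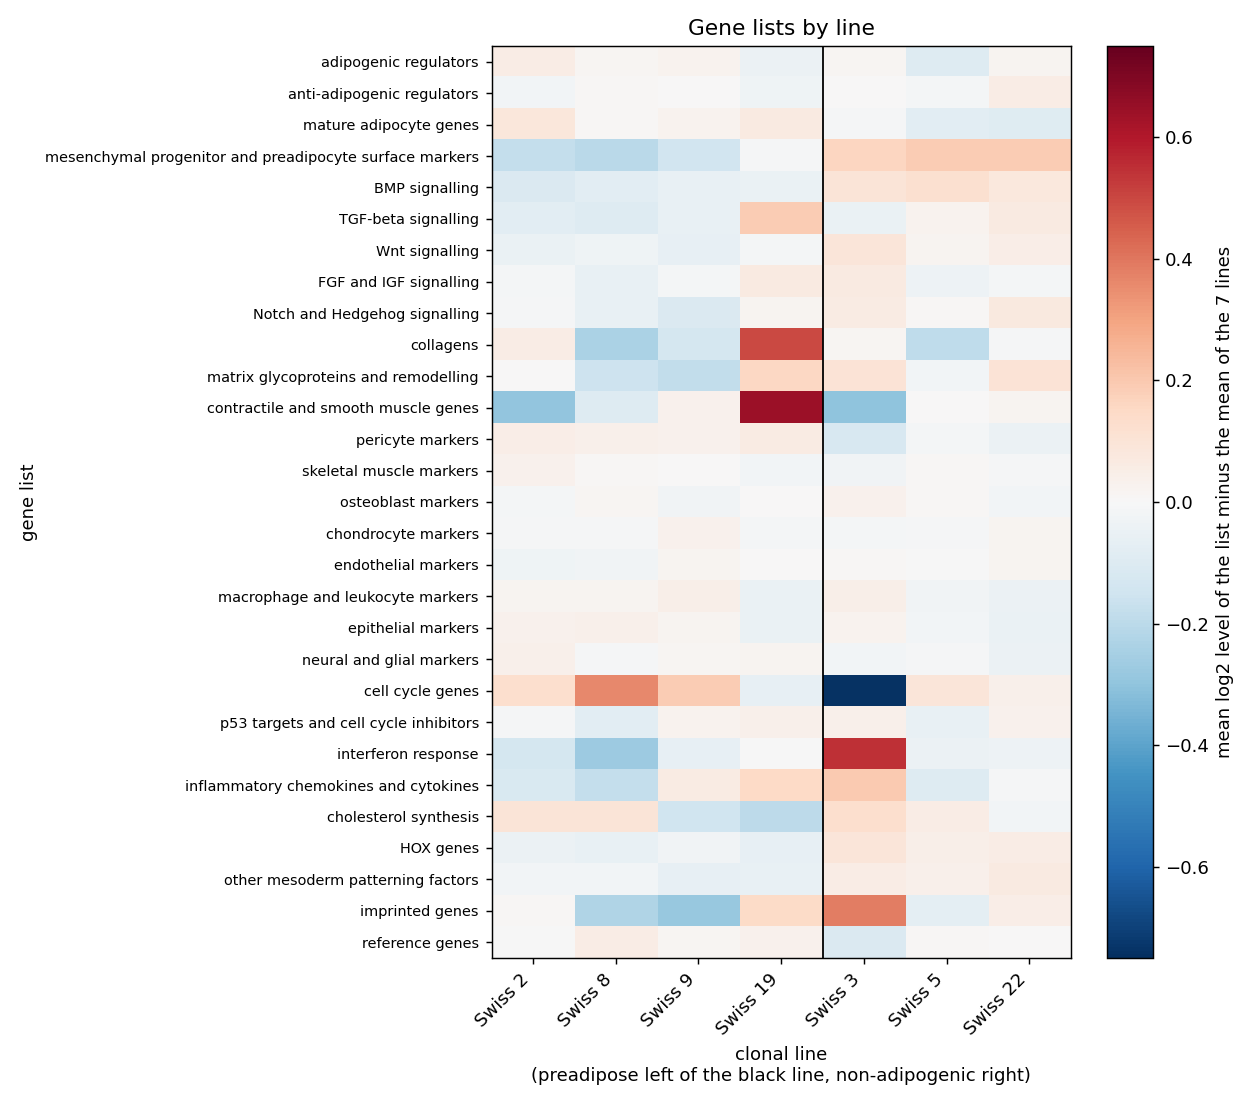
Mean log2 level of each of the 29 gene lists (vertical axis) in each clonal line (horizontal axis), minus the mean of the 7 lines, with the colour scale in log2 units. Swiss 3 is lowest for cell cycle genes (-0.742) and highest for interferon response genes (0.548), and Swiss 19 is highest for contractile genes (0.64) and collagens (0.495).

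Preadipose lines also differed from each other, and Swiss 19 stood farthest apart. By the F test on arrays, 4212 genes differed among the 4 preadipose lines. The line farthest from their mean was Swiss 19 for 1580 of these genes, Swiss 2 for 1347, Swiss 9 for 728 and Swiss 8 for 557. The widest range was that of Myl9, a myosin light chain of contractile cells, with a scaled intensity of 934 in Swiss 2 and 9534 in Swiss 19. Fhl1, a muscle LIM protein, was at 2876 in Swiss 19 and between 69.5 and 279 in the others, not above background in Swiss 2. Prss23, a serine protease, was at 1047 in Swiss 2 and 9295 in Swiss 19, and Cd24a, a surface glycoprotein, at 252 and 4434. Brinp3 was high in Swiss 9 (2581) and Swiss 19 (2087) and not above background in Swiss 2 (16.7). The list means of contractile genes (0.64) and collagens (0.495) were highest in Swiss 19 as well. Only Swiss 19 of these lines was on bright arrays. With brightness as a term, which Swiss 3 alone can estimate, 3092 genes differed, and 1569 among the 3 lines on dim arrays. Without normalization between arrays the F test called 12732 genes.

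Among the non-adipogenic lines Swiss 3 stood apart. The F test called 2976 genes, and Swiss 3 was farthest from the class mean for 2161 of them, against 483 for Swiss 5 and 332 for Swiss 22. The 5 genes with the widest range were all highest in Swiss 3. Mest, an imprinted hydrolase, was at a scaled intensity of 3277 in Swiss 3, 1662 in Swiss 5 and 142 in Swiss 22. Dpt, the matrix protein dermatopontin, was at 9706 in Swiss 3 against 2520 and 1595. Fap, a surface protease of activated fibroblasts, was at 4944 against 1294 and 614, and Clu, the secreted chaperone clusterin, at 6509 against 1771 and 927. Meg3, an imprinted noncoding RNA, was at 16493 against 3161 and 3996. The F test with brightness as a term called 1549 genes, and 2277 within the bright arrays, against 11527 without normalization between arrays. Of all genes, 1873 differed among the lines of both classes.

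The class held a small share of the sum of squares of an average gene, but the shares were not adjusted for degrees of freedom. The classes have fewer of these than the lines or the arrays, so noise alone would give the class the smallest share. The shares therefore do not show that lines of a class differ more than the classes do. Over all genes, the median share of the sum of squares was 6.74% between classes, 32.5% between lines of a class and 52.1% between arrays of a line. Without the dimmest 40% of genes the shares were 12.4%, 39.8% and 33.9%. For the 279 genes called between the classes they were 81.2%, 8.99% and 7.63%, which partly follows from how these genes were chosen. Of these 279, 88 also differed among preadipose lines, 70 among non-adipogenic lines and 153 in neither.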

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

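The counts and sizes with brightness taken out were chosen after the result was seen. The 35 splits of the lines for the class comparison were planned, but the rule for reading them was written after the count was seen. The other tests here were chosen before their results were seen.

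Probe sets that no gene name was given for also held a class difference. Of 9160 such probe sets, 14 passed the threshold when all 45037 probe sets were fitted on their own with limma, 5 of them higher and 9 lower in preadipose lines. They belong to no comparison of named genes, and their genes are not named here.

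In 2 of the 29 gene lists, 1 of the 4 preadipose lines lay far from the other 3, by the ratio of its gap to the range of the class. In the TGF-beta list, Swiss 19 was high, with a list mean of 0.19 against -0.077 ± 0.020 (SD, n = 3 lines) in the others and a ratio of 0.861. In the chondrocyte list, Swiss 9 was high by a small amount, at 0.034 against -0.0099 ± 0.00255, with a ratio of 0.893. Of the 72 named genes 0 stood out in this way. Chance marks about 5% of groups in this way.

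The first pattern weighed was the set of 279 genes called between the classes, since 3 of the 4 preadipose lines were on dim arrays. Of the 35 splits of the 7 lines into 4 and 3, 1 gave as many calls, the real one. This makes chance an unlikely source of the count but cannot exclude it. A comparison of 35 splits can give no p below 0.0286, and the rule for reading it was written after the count was seen. The highest of the other splits, with 52 calls, set Swiss 3, Swiss 5, Swiss 22 and Swiss 19 against Swiss 2, Swiss 8 and Swiss 9, which nearly follows brightness. Brightness as the whole cause was weighed within Swiss 3, where the bright array minus the dim ones was set against the class difference of the called genes. The slope was 0.0124 ± 0.0112 (SD over resampled genes), while brightness would need a negative slope. The spike level differed by 0.913 on the log2 scale within Swiss 3 and by -0.64 between the class means. The slope argues against brightness as the whole cause only over that step. The contrast rests on 1 bright array, and its SD leaves out the spread between arrays. That array had a mean intensity of 71.97, below all arrays of Swiss 22 and Swiss 19, so it cannot settle the question. With brightness taken out, the median size of the 279 differences, 0.62 before, was 0.64 with the block. It was 0.63 and 0.57 with Swiss 3 in the block by its dim or its bright arrays alone, and 0.60 with the spike level as a covariate. In the same order the calls were 314 (211 among the 279), 239 (154), 19 (8) and 115 (77). The median standard error was 0.0875 before and 0.0999, 0.0923, 0.133 and 0.104 after. Swiss 19 was on bright arrays and the other preadipose lines on dim ones, so a gene that followed brightness would spread within that class. Such a gene was unlikely to be called. The like sizes were therefore largely set by how the 279 genes were picked and are no separate evidence on brightness. Copy number of neighbouring genes stays open for part of the pattern: 31.5% ± 2.83 of called genes had a called gene of the same direction among the 10 nearest on either side, above the highest of the random placements (24.7%) but a minority of the genes.

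The second pattern was the low level of cell cycle genes and the high level of interferon genes in Swiss 3, whose omission moved both list medians most, though the interferon call was also lost without Swiss 2 (adjusted p = 0.0539) and without Swiss 8 (adjusted p = 0.0862). The number of lists called between the classes does not exclude chance, since 30 of 35 splits of the lines called at least 2 lists and the highest of the other splits called 6. Brightness was argued against over the step within Swiss 3, a contrast that rests on 1 bright array. Its bright and dim arrays differed by at most 0.0495 times the distance of Swiss 3 from the other lines. The dim arrays differed about as much from each other (0.0516). A list of 18 growth arrest genes fixed for this test, such as Gas6 and Ccng2, was higher in Swiss 3 by a median of 0.25 on the log2 scale, at the 99.8th percentile of 10000 matched random lists, with 13 of 18 genes higher. Random lists do not keep genes that move together, so this percentile can be too high. It also sets Swiss 3 alone against the other lines, so it does not decide the question. The list of cell cycle inhibitors and p53 targets did not set Swiss 3 apart. Relative to the mean of the lines it was at 0.0393 in Swiss 3, 0.04 in Swiss 19 and 0.0344 in Swiss 22. Swiss 3 cultures nearer to growth arrest at harvest and a lasting property of that clone both stay open.

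The third pattern was the order of the preadipose lines, since Swiss 19, on bright arrays, was the highest of them for Myl9, Prss23, Fhl1 and Cd24a and for the contractile list. Regrouping the arrays excluded chance for the counts only against the spread between arrays of a line, which may be technical: 1 of 100 drawn splits, the real one, called as many as 4212 genes among preadipose lines and the highest other called 1514, and the same held for the 2976 among non-adipogenic lines (1 of 100, highest other 2134). If brightness set the order, genes that climb with it across the 4 lines would also be higher on the bright than on the dim arrays of Swiss 3, but only 46.9% ± 0.742 (SD over resampled genes) of the 4212 genes had the same sign. This SD leaves out the spread between arrays. The contrast rests on 1 bright array, at a mean intensity of 71.97 against 156.7 and 141.6 in Swiss 19, so it cannot settle the question. Brightness and a biological difference between the clones both stay open and were not tested further.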

How the results depend on the processing

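Scaling before the pseudocount, the spike covariate, brightness as a block, with Swiss 3 as 2 means or by 1 part alone, the fits within the dim and bright arrays and the comparison with genes of like mean level were chosen after seeing the data. Of the 279 genes called between the classes, 246 kept their direction without normalization and 264 with arrays centred on their medians, and without the dimmest genes 274 were tested and all kept it. In the other alternatives all 279 did, but their line means did not overlap between the classes, so leaving out a line could not turn them and the fits by brightness hardly could. The calls rested on quantile normalization. With every array as a replicate 279 of the 279 were called and with the line as a random block 276, among more genes. The first of these fits counts arrays of a line as independent, and the second uses 1 correlation of 0.258 for all genes. Genes called on line means could hardly be lost in them, so these counts do not show robustness. Signal near background limits dim genes such as Zfp423. Where no construction of an alternative shows it, the cause was not tested.

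Against 106 higher and 173 lower, the class counts were 1444 higher and 1644 lower with every array as a replicate, 972 higher and 1089 lower with the line as a random block, 0 higher and 2 lower without normalization between arrays, 1 higher and 6 lower with arrays centred on their medians, 26 higher and 41 lower with a smaller pseudocount, 58 higher and 140 lower with a larger one, 182 higher and 262 lower without the dimmest genes. They were 1 higher and 1 lower with a minimum fold of 1.5, 317 higher and 458 lower with a threshold of 0.1, 36 higher and 64 lower with scaling before the pseudocount, 52 higher and 63 lower with the spike level as a covariate, 11 higher and 8 lower with brightness as a block and Swiss 3 by its bright array alone, where the dim part holds 1 class, 189 higher and 189 lower within the dim arrays, 0 higher and 0 lower within the bright arrays. With a line left out they ran from 17 and 38 without Swiss 22 to 182 and 288 without Swiss 19, in fits with fewer lines. With an array left out the total ran from 217 to 326.

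The replicate numbers did not pair the arrays: over 57 pairs of same-numbered arrays of different lines, the correlation of deviations from the line means had a median of 0.00080 and ran from -0.051 to 0.071, with 0 pairs over 0.1. With the replicate block the class counts were 109 and 183, 274 of them among the 279, Smad3 was the only one of the 43 called named genes that did not pass (adjusted p = 0.0526), Zfp423 was at 0.085, and 4043 and 2916 genes differed among preadipose and non-adipogenic lines. With arrays as replicates and a replicate block the counts were 1376 higher and 1545 lower.

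Among preadipose and non-adipogenic lines, 12732 and 11527 genes differed without normalization and 12490 and 10751 with arrays centred on their medians. 1569 differed among preadipose lines within the dim arrays, and 1549 among non-adipogenic lines with brightness as a block. The shares between classes, lines and arrays were 13.9%, 63.5%, 13.3% without normalization, 12.1%, 60.5%, 17.6% with median centring, 12.4%, 39.8%, 33.9% without the dimmest genes and 8.32%, 27.7%, 54.8% without Swiss 19. With a line left out, the share between classes ran from 6.92% to 8.32%, that between lines from 27.7% to 31.6% and that between arrays from 51.8% to 54.8%.

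The number of lists called by camera, 2 in the fit reported, was 4 without normalization, 7 with median centring, 4 without the dimmest genes, 1 with scaling before the pseudocount, 5 with the spike covariate, 0 with an estimated correlation and 0 without Swiss 3, and at most 2 with another line left out. The medians given for no normalization and for median centring are not relative to other genes. Genes of like mean level to the cell cycle list had medians of -0.61 and -0.48 there. The list lay 0.28 above them, a value that is the same in both scalings by construction. The median log2 difference of lists whose sign or call changed, or that bound the range with a line left out, was as follows. With an estimated correlation, it was 0.33 for cell cycle genes and -0.14 for interferon response. With fry, it was -0.10 for BMP signalling, -0.032 for Wnt signalling, 0.33 for cell cycle genes, -0.14 for interferon response and -0.054 for other mesoderm patterning factors. With the line as a random block, it was -0.0034 for anti-adipogenic regulators, -0.10 for BMP signalling and -0.0036 for Notch and Hedgehog signalling. With the replicate block, it was -0.00042 for Notch and Hedgehog signalling. Without normalization between arrays, it was -0.27 for adipogenic regulators, -0.37 for anti-adipogenic regulators, -0.14 for mature adipocyte genes, -0.42 for TGF-beta signalling, -0.18 for Notch and Hedgehog signalling, -0.38 for collagens, -0.29 for contractile and smooth muscle genes, -0.029 for pericyte markers, -0.085 for skeletal muscle markers, -0.058 for chondrocyte markers, -0.090 for macrophage and leukocyte markers, -0.062 for epithelial markers, -0.030 for neural and glial markers, -0.26 for cell cycle genes, -0.37 for p53 targets and cell cycle inhibitors, -0.34 for interferon response and -0.64 for cholesterol synthesis. With arrays centred on their medians, it was -0.14 for adipogenic regulators, -0.24 for anti-adipogenic regulators, -0.014 for mature adipocyte genes, -0.29 for TGF-beta signalling, -0.048 for Notch and Hedgehog signalling, -0.26 for collagens, -0.53 for matrix glycoproteins and remodelling, -0.17 for contractile and smooth muscle genes, 0.10 for pericyte markers, 0.031 for osteoblast markers, 0.070 for chondrocyte markers, 0.053 for endothelial markers, 0.10 for neural and glial markers, -0.13 for cell cycle genes, -0.24 for p53 targets and cell cycle inhibitors, -0.51 for cholesterol synthesis and -0.57 for reference genes. Without the dimmest genes, it was -0.17 for BMP signalling, -0.022 for Notch and Hedgehog signalling, -0.0097 for macrophage and leukocyte markers, -0.057 for neural and glial markers and -0.20 for HOX genes. With the mean of a gene's probe sets, it was -0.022 for anti-adipogenic regulators, -0.0044 for TGF-beta signalling and 0.0081 for endothelial markers. With scaling before the pseudocount, it was -0.017 for anti-adipogenic regulators and -0.28 for interferon response. With the spike level as a covariate, it was -0.021 for adipogenic regulators, -0.029 for anti-adipogenic regulators, 0.069 for mesenchymal progenitor and preadipocyte surface markers, 0.19 for collagens, 0.53 for contractile and smooth muscle genes, -0.019 for skeletal muscle markers, -0.012 for macrophage and leukocyte markers, -0.0076 for epithelial markers, -0.020 for p53 targets and cell cycle inhibitors and -0.17 for cholesterol synthesis. With brightness as a block, it was 0.033 for mesenchymal progenitor and preadipocyte surface markers and 0.35 for contractile and smooth muscle genes. Within the dim arrays, it was -0.0090 for Notch and Hedgehog signalling, -0.094 for collagens, 0.0077 for osteoblast markers, -0.0083 for neural and glial markers and 0.0022 for other mesoderm patterning factors. Within the bright arrays, it was -0.057 for anti-adipogenic regulators, 0.032 for mesenchymal progenitor and preadipocyte surface markers, 0.62 for collagens, 0.020 for matrix glycoproteins and remodelling, 0.60 for contractile and smooth muscle genes, -0.025 for skeletal muscle markers, 0.0059 for osteoblast markers, -0.049 for macrophage and leukocyte markers, -0.018 for epithelial markers, 0.13 for cell cycle genes, -0.028 for interferon response, -0.26 for cholesterol synthesis and 0.023 for reference genes. Without Swiss 5, it was -0.029 for anti-adipogenic regulators, 0.022 for osteoblast markers, 0.040 for chondrocyte markers, 0.51 for cell cycle genes and -0.25 for interferon response. Without Swiss 22, it was 0.013 for anti-adipogenic regulators, -0.018 for endothelial markers and -0.10 for inflammatory chemokines and cytokines. Without Swiss 3, it was -0.053 for TGF-beta signalling, 0.0053 for endothelial markers, 0.074 for cell cycle genes, 0.020 for interferon response and 0.048 for inflammatory chemokines and cytokines. Without Swiss 2, it was 0.12 for TGF-beta signalling, -0.039 for FGF and IGF signalling and -0.14 for interferon response (adjusted p = 0.0539). Without Swiss 8, it was 0.0089 for FGF and IGF signalling, -0.0020 for skeletal muscle markers and -0.12 for interferon response (adjusted p = 0.0862). Without Swiss 19, it was 0.031 for skeletal muscle markers. Without Swiss 9, it was -0.023 for osteoblast markers and -0.019 for chondrocyte markers.

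No named gene that was called between the classes changed sign, which line means without overlap settle for the fits with a line left out. The log2 difference of named genes that were not called between the classes, where it changed sign or bound the range with a line left out, was as follows. With every array as a replicate, it was -0.028 for Myl9. With arrays as replicates and a replicate block, it was -0.046 for Myl9. Without normalization between arrays, it was -0.090 for Csf1r, -0.036 for Cybb, -0.049 for Pgk1, -0.13 for Cyc1 and -0.46 for Myl9. With arrays centred on their medians, it was -0.33 for Myl9. With the smaller pseudocount, it was -0.42 for Brinp3. With scaling before the pseudocount, it was -0.24 for Brinp3. With the spike level as a covariate, it was 0.10 for Cd24a and 0.59 for Prss23. With brightness as a block, it was 0.16 for Prss23. Within the dim arrays, it was -0.078 for Fhl1 and -0.046 for Brinp3. Within the bright arrays, it was -0.049 for Cybb, 0.34 for Cd24a, 1.07 for Prss23 and 0.11 for Meg3. Without Swiss 19, it was -0.41 for Myl9 and -0.086 for Fhl1. Without Swiss 2, it was 0.53 for Myl9, 0.79 for Fhl1 and 0.75 for Brinp3. Without Swiss 9, it was -0.11 for Brinp3.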

Other observations

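The tests of the ATF4 target list and of neighbouring genes were fixed before their results were seen, after the genes that prompted them had been noticed. The genes named here fall outside the naming rule unless named above and were chosen after their values were seen. The values along the stretch that ends at Pdgfra were looked up after the neighbour test.

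Among genes of amino acid supply and of the amino acid stress response, 5 that passed the threshold were higher in preadipose lines. Asns, asparagine synthetase, differed by 1.43 on the log2 scale (SE 0.248, limma adjusted p = 0.0421), Eif4ebp1, which restrains translation, by 1.29 (SE 0.110, adjusted p = 0.00505), and Atf5 by 1.54. Trib3 passed as well, with 0.79. Atf4, the transcription factor that drives these genes, differed by 0.65 (SE 0.120, adjusted p = 0.0494), and by -0.052 without normalization between arrays, where genes of like mean level had a median of -0.74. Of the enzymes of serine and folate metabolism, which were not tested as a group, some were on the same side without passing the threshold. These were Mthfd2 (0.96, adjusted p = 0.0940), Shmt2 (0.79, adjusted p = 0.0915), Psat1 (0.90, adjusted p = 0.107) and Phgdh (0.63, adjusted p = 0.155). So were the transfer RNA synthetases Gars (0.79), Tars (0.75) and Cars (0.58).

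From Asns, Atf5 and Eif4ebp1, the hypothesis was formed that ATF4 targets are higher in preadipose lines as a group. A list of 39 further targets that left out those 3 genes and Trib3 had 38 measured members, of which 35 were higher, 21 of them with no overlap of line means and 0 with no overlap in the other direction. The median log2 difference was 0.39, and -0.12 without normalization between arrays, where genes of like mean level had -0.57 and 35 of the 38 lay above them. With the preset correlation camera gave 2.65e-14, and with brightness as a block 3.21e-20. With an estimated correlation p was 0.0551, above the 0.05 fixed for both in advance, so the test does not decide. Only Atf4 itself was called in the list. A raised amino acid response in preadipose lines remains a candidate explanation, and medium age or cell density could raise the same genes.

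Clonal lines of an immortalized strain can differ in copy number, which would move neighbouring genes together. For each line, the difference from the mean of the other lines was averaged over every run of 40 neighbouring genes among 10898 brighter genes. In 6 of 7 lines the largest such mean exceeded that of all 1000 random gene orders, the exception being Swiss 19 (0.232 against 0.259). The largest means were -0.445 in Swiss 2 and 0.354 in Swiss 3, both over the run from Wdr19 to Tmem165. Because each line was set against the mean of the others, opposite means over the same run are not independent. In Swiss 8 (-0.29) and Swiss 22 (0.284) it was the run from Tlr6 to Pdgfra, in Swiss 5 (0.283) that from Cenpk to D13Ertd608e and in Swiss 9 (0.241) that from Rnf181 to Stambp, where all 40 genes had the same sign. Copy number differences between the clones are therefore a candidate explanation for part of the line differences, though shared regulation of neighbours could give the same and no DNA was measured.

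The run that ends at Pdgfra was also the one with the largest mean class difference, -0.451, where the largest of 1000 random orders was 0.259. In all, 118 runs, which can overlap one another, exceeded every random order in size. Leaving out Pdgfra, 34 of the 39 other genes were lower in preadipose lines, by a mean of -0.407. The run was picked after its means were seen, so this count and mean largely restate that choice and are no separate support. Of the 39 genes, 4 were called: Chic2 (-0.97, adjusted p = 0.0217), Fip1l1 (-0.80, adjusted p = 0.00709), Rasl11b (-0.48, adjusted p = 0.0469) and Usp46 (-0.33, adjusted p = 0.0441). The mean of these 39 genes, relative to the 7 lines, was -0.361 in Swiss 2, -0.223 in Swiss 8, -0.0588 in Swiss 9 and -0.0549 in Swiss 19, against 0.269 in Swiss 3, 0.21 in Swiss 5 and 0.22 in Swiss 22. The log2 level of Pdgfra was 8.446 in Swiss 9, about as low as in Swiss 2 (8.337) and Swiss 8 (8.216). Yet the stretch was far less low in Swiss 9. Pdgfra was at 9.025 in Swiss 19 and at 10.9, 10.56 and 10.86 in Swiss 3, Swiss 5 and Swiss 22. The low Pdgfra of the preadipose lines may belong in part to a change of the whole stretch, a hypothesis formed from these data. The 6 lines of the neighbour test do not count in its favour. Lows and highs over 1 run mirror each other there, and Swiss 5 and Swiss 9 had their largest means elsewhere. Pdgfra itself differed by -2.27, several times more than the stretch.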
